A study of Mus musculus with 10 samples.

How the data were processed

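Gene expression was measured on 10 Agilent 2-colour mouse arrays with 45018 spots each, on RNA from small intestinal crypts and from organoids, which are crypt cells grown in culture as miniature epithelia. Per the labels, 4 arrays carried crypt RNA from mice with Lgr4 and Lgr5 deleted and crypt RNA from wild type mice on the same array. These made up 2 biological replicates, each hybridised on a pair of arrays with the dyes swapped. The other arrays carried organoid RNA in Cy5 against a commercial mouse reference RNA in Cy3. They were 2 wild type and 2 deleted organoid cultures, 1 culture grown without R-spondin and 1 grown with it. All samples were taken 1 day after the deletion or the withdrawal. Deletion in mice used a Cre gene under a promoter that xenobiotics switch on, and deletion in organoids used VillinCre with tamoxifen. The labels do not say whether the wild type mice or cultures received these agents. A deletion of Apc that the series description names was not analysed here.

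The authors' scanner files hold raw spot and local background values in the unit intensity, and processed signals, also intensity, that the scanner software had corrected for background and for dye. Per the file headers, the software was Agilent Feature Extraction 10.5.1.1, whereas the authors' processing notes name 8.5.1.1. The deposited log ratio column is the log10 of the red over the green processed signal, and the deposited series matrix holds the same log10 ratios. Compared with the scanner files, the matrix had the sign turned for the 2 crypt arrays that carried deleted RNA in Cy3, so all 4 crypt columns read deleted over wild type. No array had a saturated spot.

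The 43379 gene probe spots of each array held 41174 distinct probes. Of these spots, 28661 were named through the RefSeq accession in the file, matched without its version to the mouse reference table. Current symbols named 5396 spots, older symbols named 952, and 8370 kept the name in the file. This gave 28034 distinct names. Chromosomes are those of the mouse GRCm38 assembly of that table.

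Raw intensities were background-corrected in limma 3.58.1 under R 4.3.3, with files read by data.table version 1.17.8, with the normexp method and an offset of 50. The crypt and R-spondin arrays gave mean pixel signals, and the files of the other organoid arrays hold only median pixel signals, which were used there. Log2 ratios were then normalised by loess within each array, and control spots were left out. Spots of the same probe were averaged, and each gene was represented by its brightest probe over the arrays of the comparison. A probe was tested where it was well above background on every array of at least 1 of the groups compared, by the scanner software's own call in the channel of that group's RNA. Dye-swapped arrays were turned to deleted over wild type and averaged, so that each crypt replicate gave 1 value. Where 1 array of a pair had no usable spot, the other array gave that value.

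Spots that the scanner software marked as outliers, in the spot or in its local background, were left out before the background fit. This step was changed after the results of a first version had been seen. In that version a few spots with very high local background set the fitted background of a whole array. On the deleted-in-Cy5 array of crypt replicate 1 the fitted red background was -1264 and the fitted green background was -808. On deleted organoid array 1 the fitted red background was -711. With marked spots left out, the same 3 values were 10.2, 24.3 and 8.30. The first version is kept among the alternatives. The marked share ranged from 2.48% to 6.94% of gene probe spots per array.

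The Cy3 reference channel of the 4 organoid deletion arrays was unlike that of the other arrays. Their 153 negative control spots had Cy3 medians of 6094, 6564, 5883 and 6179, against 90 to 117 on the other 6 arrays. Their gene probe spots were bright too, with Cy3 medians of 1830 to 1933 against 131 to 201, but lay below the negative controls. Only 1589 to 1847 probe spots were called above background in Cy3 on these 4 arrays, against 20345 to 21987 in Cy5. Changes of -2 placed in the raw organoid signals came back by ratio smaller on the median than by Cy5, and more widely spread over genes (SD 0.586 against 0.334), so single genes can also be overstated by ratio. After this had been seen, the Cy5 channel alone was added for the organoid comparisons, with normexp and quantile normalisation between arrays. Counts and lists are given by both measures, and genes by the measure that named them with the other beside it where the gene was above background in both groups. The ratio remains the planned measure. The number of arrays limits the precision of every value.

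Crypt values were tested against 0, and deleted organoids against wild type organoids, with limma's linear model and moderated statistic, two-sided. Benjamini-Hochberg adjustment was applied over all genes of a comparison, with a threshold of 0.05. The residual degrees of freedom were 1 for crypts and 2 for organoids, and the prior added 4.88 and 2.45. The difference of the deletion effects was tested in a joint fit of the 2 crypt replicate values and the 4 organoid arrays. R-spondin withdrawal had 1 array per group and no test. Its genes were counted at an absolute log2 difference of 1 or more, beside the same count between replicate organoid arrays.

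The 21 gene lists were Wnt target genes, Lgr5 stem cell markers, Paneth cell, goblet cell, enteroendocrine, tuft cell and enterocyte markers, cell cycle genes, ribosome biogenesis genes, cholesterol synthesis genes, Notch pathway and secretory fate genes, BMP and TGF-beta response genes, MAPK response genes, immediate early and heat shock genes, p53 target genes, aryl hydrocarbon receptor targets, interferon response genes, and immune cell, stromal and muscle, endothelial, and erythroid and mesothelial-fat markers. Lgr4 and Lgr5 were in none of them. The Wnt and stem cell lists shared 8 genes. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, were run beside it. With an estimated correlation, camera rests on the residual degrees of freedom, 1 in crypts, 2 in organoids and 3 in the joint fit. Few lists can pass it, and a call lost there does not show that its genes moved together. For R-spondin withdrawal, each list's median was placed among 10000 random lists matched on brightness in 20 bins, and the range holding 95% of them was taken as chance. Signatures were the 100 genes per direction with the most extreme moderated statistic and the same sign in both replicates, without Lgr4 and Lgr5.

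The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The naming rule gave Lgr4, Lgr5 and Lgr6. For each tested comparison it added, per direction, the 10 genes with the largest change among those past the threshold, filled up by the lowest p where fewer passed. Such a gene had to move the same way in both crypt replicates. In organoids both deleted cultures had to lie on one side of both wild type cultures. For withdrawal it added the 10 largest differences per direction among genes above background on both arrays, and it allowed up to 4 members of each list discussed. Identifiers that are not approved gene symbols were counted and not named. For a gene not above background on all arrays of 1 group, the fold is given as a bound. The bound sets that group at the lowest signal called above background on its array, or at its own signal where that was higher. It is taken from the Cy5 signals, after loess and Aquantile normalisation and after quantile normalisation, and the smaller of the 2 folds is given. No bound is given where it exceeded the measured ratio change, as for Snai2 and Tmem87a in deleted organoids and for Lgr5, Tnfrsf19 and Pcdh8 without R-spondin. For list medians by ratio the bounds come from the first of these and are set no larger than the measured change.

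The procedure was tested on simulated data with 200 genes changed. When each gene's spread was drawn from the fitted prior, a log2 change of 1 was recovered for 0 genes in crypts, 0 in organoids by ratio, 0 by Cy5 and 0 for the difference of effects. With each gene's own shrunken spread, the same 4 counts were 157, 0, 23 and 0. A log2 change of 2 was recovered with the prior spread for 197 genes in crypts, 0 in organoids by ratio, 164 by Cy5 and 0 for the difference, and with the shrunken spread for 200, 179, 198 and 119. Unchanged genes called at that size numbered 30, 0, 10 and 0 with the prior spread, and 26, 9, 16 and 9 with the shrunken spread. A list of 30 genes shifted by -0.5 gave camera p-values of 1.36e-18, 7.23e-19, 3.08e-11 and 1.27e-09 in the same 4 comparisons, and an unshifted list gave 0.192, 0.279, 0.315 and 0.345. For withdrawal, 47 of 50 shifted lists and 3 of 50 unshifted lists lay outside the random range. The simulated genes were independent of each other. The unshifted lists therefore do not show how often a list of genes that move together is called without a shift. A change of -2 placed in the raw signals came back with a median of -1.82 in crypts, -1.04 in organoids by ratio, -1.75 by Cy5 and -1.73 under withdrawal.

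The alternatives were no background subtraction, the scanner software's processed signals centred on the median, median centring in place of loess, Aquantile normalisation between arrays, no filter on dim probes, the mean of all probes of a gene, and the series matrix. Further alternatives were crypt fits on all 4 arrays with the replicate as a random block, with and without a dye term, arrays of a single dye orientation, a joint fit sharing the spread, an intensity trend with a robust prior, the slide as a block, each slide alone, 50 or 200 signature genes or only called genes, a size of 0.58, and leaving out each replicate. The correlation within crypt replicates was estimated at 0.327.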

Results

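The experiment asked what the mouse intestinal epithelium loses when Lgr4 and Lgr5, receptors for the secreted Wnt agonist R-spondin, are removed, and how that compares with taking R-spondin away. Expression was read on 10 arrays, all 1 day after the perturbation. Crypts, the pits of the intestinal epithelium that hold the stem cells, were compared on 4 arrays as 2 deleted and wild type replicate pairs with swapped dyes. Organoids were compared as 2 deleted against 2 wild type cultures, and as 1 culture without against 1 culture with R-spondin. In the Cy5 channel, 62.2% and 63.1% of gene probe spots were above background on the R-spondin arrays, and 46.9% to 50.7% on the other organoid arrays. On the crypt arrays 40.2% to 56.9% were above background in Cy5 and 48.9% to 60.02% in Cy3. In the Cy3 reference channel of the 4 organoid deletion arrays only 3.66% to 4.26% were above background, so changes are given there as ratios and also from Cy5 alone, a measure added after that had been seen. All changes are log2 values.

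The deleted genes fell in both systems. In crypts, Lgr4 on chromosome 2 changed by -1.56 (SE 0.22) and Lgr5 on chromosome 10 by -1.68 (SE 0.23), and every crypt array showed both falls. The replicate values were -1.51 and -1.61 for Lgr4, and -1.89 and -1.48 for Lgr5. The 4 arrays gave -1.51, -1.52, -1.78 and -1.45 for Lgr4, and -1.51, -2.27, -1.54 and -1.42 for Lgr5. In organoids the Lgr4 Cy5 signal was 2035 and 2846 in the wild type cultures against 198 and 355.5 in the deleted cultures. The Lgr5 signal was 1004 and 1591 against 108 and 118.5, and the 2 deleted signals were not above background. In limma the adjusted p in crypts was 0.0894 for Lgr4 and 0.0886 for Lgr5, so neither passed. In organoids Lgr4 gave -0.59 by ratio (SE 0.27, limma adjusted p 0.962) and -3.57 by Cy5 (SE 0.36, limma adjusted p 0.0833). Lgr5 had no fitted organoid value, because its spot on wild type array 2 was marked as an outlier.

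The probes for Lgr4 disagreed. A second probe gave -0.997, -0.92, -1.15 and -1.15 on the crypt arrays. In organoids its Cy5 signal was 897 and 943.5 in the wild type cultures. In the deleted cultures it was 120 and 130, not above background. Another, dim probe rose by 0.25, 0.18, 1.20 and 0.97 on the crypt arrays, and gave 0.39 and 0.15 in organoids by ratio and by Cy5. The remaining probe was not above background on any array. Without R-spondin the probe used for Lgr4 gave -0.01, with Cy5 signals of 2674.5 without and 2382 with R-spondin, but the second probe gave 0.54, with signals of 1450 and 955. Lgr5 had a Cy5 signal of 173, not above background, without R-spondin and 6455 with it. The related receptor Lgr6 was not tested in crypts and changed by 0.04 in organoids by ratio, -0.34 by Cy5 and 0.04 without R-spondin.

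The 5 named genes that passed the test in deleted crypts 1 day after deletion all rose, and they encode enzymes that metabolise foreign compounds. Cbr3 on chromosome 16 rose by 4.97 (SE 0.22), Akr1b8 on chromosome 6 by 4.45 (SE 0.22), Gsta3 on chromosome 1 by 3.69 (SE 0.24), Cyp1a1 on chromosome 9 by 3.66 (SE 0.25) and Ces1g on chromosome 8 by 3.09 (SE 0.24). Among the falling genes, none of which passed, were the stem cell genes Olfm4 at -1.81 and Slc14a1 at -2.11, with Gkn3 at -2.08, the Paneth cell gene Defa21 at -1.65, the Wnt target Slc12a2 at -1.59, and Gvin1, Gsdmc3 and Ccl9 at -2.48, -2.46 and -1.69. Other rising genes, which did not pass either, were Gstm1 at 3.09, Aldh4a1 at 2.48, Me1 at 2.38, the goblet cell gene Retnlb at 2.33 and Cyp3a13 at 2.18. Each of these genes moved the same way in 2 of 2 replicates, as the naming rule required.

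Of 12195 genes tested with limma, 6 were higher and 0 lower at an adjusted p under 0.05, and 5 of the 6 carry an approved symbol. Their adjusted p-values in limma were 0.00693 for Cbr3, 0.00782 for Akr1b8, 0.0215 for Gsta3 and Cyp1a1, and 0.0355 for Ces1g. At an unadjusted p under 0.05, limma gave 891 lower and 784 higher genes, 1675 in all where chance gives 609.75. The falling genes missed the threshold, with limma adjusted p-values from 0.0542 for Gvin1 to 0.0908 for Slc12a2, as did the other rising genes at 0.0625. The number called depended on the processing, from 0 to 338 lower and from 0 to 448 higher over the alternatives. A fit without 1 crypt replicate takes its spread from the organoid arrays alone. It cannot show whether these calls rest on 1 replicate. The 2 dye-swapped arrays of replicate 1 correlated at 0.348 across 17380 probes, those of replicate 2 at 0.919, and arrays of different replicates at 0.340 to 0.397, where probes are not independent replicates.

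**Figure D1:**
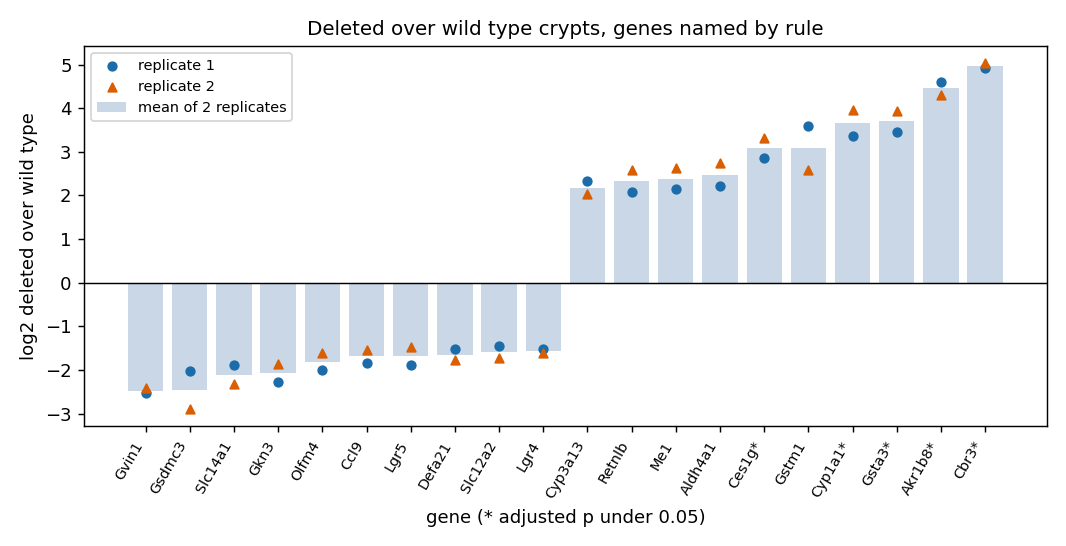
Log2 change in deleted over wild type crypts of 20 genes named by the rule, with a circle for replicate 1, a triangle for replicate 2, bars for the mean of the 2 replicates and an asterisk for a limma adjusted p under 0.05. Cbr3 rose the most of these at 4.97, and Lgr5 fell by 1.68 and Lgr4 by 1.56.

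Wnt targets, stem cell and Paneth cell markers and cell cycle genes were lower in deleted crypts. Enterocyte and tuft cell markers, interferon response genes and immune cell markers were higher, with aryl hydrocarbon receptor targets, the genes that xenobiotics induce. These list calls held in camera at the preset correlation between genes, and none of the 9 held with an estimated correlation, at a camera adjusted p of 0.622 for each. The estimate was below 0 for the Wnt, stem cell and tuft cell lists, at -0.04, -0.02 and -0.06. It was thus not the estimate itself that removed those calls, and the test had 1 residual degree of freedom. Without crypt replicate 1 the Paneth cell, tuft cell and cell cycle calls were lost too, at medians of -0.12, 0.16 and -0.18. Wnt targets included Slc12a2, Cd44 at -1.37, Sox9 at -1.23 and Tnfrsf19 at -0.83. Paneth cell genes included Ang4 at -1.45, Defa22 at -1.15 and Cd24a at -1.01. Rising genes included the enterocyte genes Ada at 2.31, Fabp1 at 1.53 and Papss2 at 1.37, the T cell genes Ccl5 at 2.46, Cd7 at 2.11, Gzma at 1.79 and Cd3d at 1.70, the interferon genes Oasl1 at 1.40, Oasl2 at 1.38, Usp18 at 1.36 and Zbp1 at 1.28, and Ahrr at 2.97, Gsta2 at 1.83 and Gsta1 at 1.69.

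The median change was -0.48 for 24 Wnt targets (20 below 0, camera adjusted p 1.17e-05), -0.69 for 28 stem cell markers (25 below 0, 5.73e-10), -0.76 for 18 Paneth cell markers (17 below 0, 2.12e-06) and -0.36 for 43 cell cycle genes (37 below 0, 8.91e-05). It was 0.60 for 31 enterocyte markers (1 below 0, 2.31e-11), 1.56 for 9 aryl hydrocarbon receptor targets (0 below 0, 7.61e-10), 0.63 for 21 interferon response genes (2 below 0, 5.72e-09), 1.24 for 24 immune cell markers (2 below 0, 1.92e-13) and 0.28 for 12 tuft cell markers (camera adjusted p 0.0188). Adjusted over the list alone, limma called 3 Wnt targets, 13 stem cell markers and 4 Paneth cell markers lower, with 1 stem cell marker higher. It called 8 enterocyte markers, 6 aryl hydrocarbon receptor targets, 8 interferon genes and 15 immune cell markers higher, against 1 aryl hydrocarbon receptor target and 0 members of the other lists over all genes tested. The Paneth cell median varied between arrays, at -1.87 and -1.01 in replicate 1 and -0.22 and 0.14 in replicate 2. The enterocyte median was 0.93 and 0.80 in replicate 1 and 0.32 and 0.50 in replicate 2. The arrays read whole crypt preparations, so in these lists a changed mix of cells cannot be told apart from changed expression.

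The other crypt lists did not pass camera. The medians were -0.05 for goblet cell markers (adjusted p 0.836), 0.15 for enteroendocrine markers (0.452), 0.09 for ribosome biogenesis genes (0.327), -0.03 for cholesterol synthesis genes (0.783), -0.35 for Notch pathway genes (0.101), 0.12 for MAPK response genes (0.380), 0.01 for immediate early and heat shock genes (0.672) and 0.12 for p53 targets (0.423). They were -0.18 for stromal and muscle markers (0.288) and -0.15 for endothelial markers (0.957). The BMP and TGF-beta genes had a median of -0.03 and a mean of 0.005 (camera upwards, adjusted p 0.957). The 2 measured erythroid and mesothelial-fat markers, with a median of 0.80, were too few to test. Their median was 1.41 and 1.78 on the arrays of replicate 1, but -0.08 and 0.10 on those of replicate 2.

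Organoids with Lgr4 and Lgr5 deleted had lower expression of Wnt target genes, stem cell markers and cell cycle genes. As the labels do not say whether the wild type cultures received tamoxifen, its effect cannot be separated from the deletion. None of the 3 list calls held with an estimated correlation, at camera adjusted p-values of 0.524, 0.671 and 0.671 by ratio and 0.249, 0.249 and 0.509 by Cy5. The cell cycle medians were -0.50 by ratio and -0.72 by Cy5, where the 2 deleted cultures differed from each other by 0.38 and 0.70. The Wnt target Axin2 fell to signals below background in the deleted cultures, at least 6.99-fold lower by its Cy5 signals. The stem cell marker Olfm4 fell by 1.66 on the ratio and by 4.42 in Cy5. Rgcc, a cell cycle regulator that is not in the cell cycle list, fell by 1.76 and by 4.56. Nrn1, which is in the stem cell list, rose instead, by 2.34 on the ratio and by 4.98 in Cy5.

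By ratio, limma called 0 of 12874 genes lower and 0 higher, with a smallest adjusted p of 0.363, and 229 lower and 268 higher at an unadjusted p under 0.05, 497 where chance gives 643.7. By Cy5, limma called 1 lower and 4 higher, with 574 lower and 439 higher unadjusted. The called genes were Rgcc (SE 0.33, limma adjusted p 0.0262), Nrn1 (SE 0.35, 0.0262), H2-Bl at 4.04 (SE 0.21, 0.0144), Dusp16 at 3.94 (SE 0.25, 0.0250) and Gas6 at 3.35 (SE 0.26, 0.0278), each with both deleted cultures on one side of both wild type cultures, as the naming rule required. By ratio the last 3 gave 1.71, 1.32 and 2.13. Another tested Dusp16 probe gave 0.07 by Cy5 and 0.24 by ratio, so that call rested on 1 probe. Axin2 and Olfm4 did not pass by Cy5, with limma adjusted p-values of 0.0949 and 0.116. Leaving out a wild type culture changed the ratio counts to 122 lower and 9 higher without replicate 1, and 65 and 3 without replicate 2.

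Further genes named by the rule did not pass by either measure. By ratio, with Cy5 in brackets, the falling ones were Kank1 at -4.27 (-0.02), Rbm45 at -2.87 (-2.30), Dnmbp at -2.03 (0.49), Arhgap6 at -1.86 (-1.22), Sorbs2 at -1.46 (-1.95) and Ccnd2 at -1.23 (-1.67), with Pcdh8 at least 2.83-fold and Scgb2b20 at least 2.16-fold lower. Another Dnmbp probe gave 0.33 by ratio. The rising ones were Ppp1r3g at 2.15 (1.102) and Id4 at 2.12 (2.01), with Pm20d1 at least 4.61-fold, Crym at least 5.44-fold, Fut4 at least 3.08-fold, Khdrbs3 at least 2.69-fold and Adgrd1 at least 1.57-fold higher. By Cy5, with the ratio in brackets, the falling ones were Ceacam10 at -2.50 (-3.335), Nr2e3 at -2.38 (-0.125), Rnf43 at -2.10 (-1.01), Agr3 at -2.01 (0.49) and Cps1 at -1.94 (0.08). The rising ones were Npl at 2.76 (0.44), Cul9 at 2.36 (0.20) and Prr5l at 1.97 (0.33). Agr3 and Cps1 thus fell by Cy5 only, and the rises of Npl, Cul9 and Prr5l were small by ratio. Probes of a gene also disagreed by ratio for Me1 (-2.35 and 0.32), Sowaha (-2.06 and 1.00), Slc14a1 (-0.83 and 0.08) and Ces1g (-0.69 and 0.01), and in crypts for Bcas1 (0.32 and -0.04).

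As lists, Wnt targets in deleted organoids fell by ratio and by Cy5 alike. The same held for stem cell, Paneth cell, tuft cell, cell cycle and ribosome biogenesis genes, and interferon response genes rose, but none of the 7 calls held with an estimated correlation. The Paneth cell call was lost without wild type replicate 2, where the median was -0.07. The tuft cell call was lost without wild type replicate 1, wild type replicate 2 or deleted replicate 2, at -0.22, -0.01 and -0.18, and under 2 other ways of scaling. By ratio the medians were -0.88 for 22 Wnt targets (19 below 0, camera adjusted p 1.64e-11), -0.38 for 28 stem cell markers (20 below 0, 1.69e-06), -0.34 for Paneth cell markers (0.00308), -0.12 for tuft cell markers (0.0134, but 0.03 with the processed signals and 0.04 with the series matrix), -0.50 for 43 cell cycle genes (41 below 0, 4.89e-14), -0.27 for ribosome biogenesis genes (2.55e-06) and 0.23 for interferon response genes (0.000239). With the 5 Wnt targets not above background in deleted cultures at their bounds, the Wnt median was -0.73. Lists were also read between the 2 cultures of each group, after the results were seen. By ratio those differed by up to 0.47 for Paneth cell, 0.36 for ribosome biogenesis and 0.23 for tuft cell genes, more than the deletion medians. The largest differences were 0.38 for cell cycle genes, 0.22 for stem cell markers, 0.15 for Wnt targets and 0.12 for interferon response genes. With an estimated correlation the camera adjusted p-values were 0.524 for the Wnt and interferon lists, 0.691 for the Paneth list and 0.671 for the others. Adjusted over the list alone, limma called 7 Wnt targets and 5 stem cell markers lower and 1 stem cell marker higher, against 0 over all genes. Within each slide, which held 1 wild type and 1 deleted culture, the Wnt median was -1.002 and -0.54, the stem cell median -0.53 and -0.11, and the cell cycle median -0.76 and -0.19. Over the alternatives, Cy5 included, the Wnt median ranged from -1.10 to -0.23, and without 1 culture from -0.80 to -0.52.

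By Cy5 the camera medians were -1.10 for Wnt targets (adjusted p 1.40e-18, estimated 0.249), -1.13 for stem cell markers (6.32e-18, estimated 0.249), -0.76 for Paneth cell markers (0.000396, estimated 0.567), -0.72 for cell cycle genes (1.40e-18, estimated 0.509, 43 of 43 below 0), -0.62 for ribosome biogenesis genes (1.38e-13, estimated 0.509), -0.23 for tuft cell markers (0.00850, estimated 0.527) and -0.26 for Notch pathway genes (0.0253, estimated 0.509). The medians were 0.39 for enterocyte markers (1.79e-05, estimated 0.249), 0.24 for goblet cell markers (0.0401, estimated 0.567), 0.20 for cholesterol synthesis genes (0.0117, estimated 0.567) and 0.22 for interferon response genes (0.000169, estimated 0.509). Between the 2 cultures of a group, Cy5 medians differed by up to 1.66 for Paneth cell, 0.62 for goblet cell, 0.53 for cholesterol synthesis and 0.27 for Notch pathway genes. Those differences were larger than the deletion medians. The cell cycle difference was up to 0.70, that of Wnt targets 0.31 and that of stem cell markers 0.30. Adjusted over the list alone, limma called 15 Wnt targets and 20 stem cell markers lower and 2 stem cell markers higher, against 1 stem cell marker higher over all genes. The remaining medians by ratio, none past camera, were 0.12 for goblet cell, 0.06 for enteroendocrine and -0.04 for immune cell markers, 0.16 for cholesterol, 0.13 for Notch pathway, 0.13 for BMP and TGF-beta and -0.01 for immediate early genes, 0.06 for p53 targets, -0.08 for stromal and -0.43 for the 2 erythroid and mesothelial-fat markers, which were too few to test. Median and mean differed in sign by ratio for enterocyte markers (0.02 and -0.05), MAPK genes (0.07 and -0.41, camera downwards), aryl hydrocarbon receptor targets (0.04 and -0.04, camera downwards) and endothelial markers (0.004 and -0.48, camera downwards). By Cy5 they differed for enteroendocrine markers (-0.09 and 0.12, camera upwards) and endothelial markers (0.06 and -0.07, camera downwards). The other medians by Cy5 were 0.17 for BMP and TGF-beta, -0.06 for MAPK and 0.10 for immediate early genes, and 0.05 for p53 and 0.43 for aryl hydrocarbon receptor targets. They were -0.04 for immune cell, 0.002 for stromal and -0.37 for erythroid and mesothelial-fat markers.

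**Figure D2:**
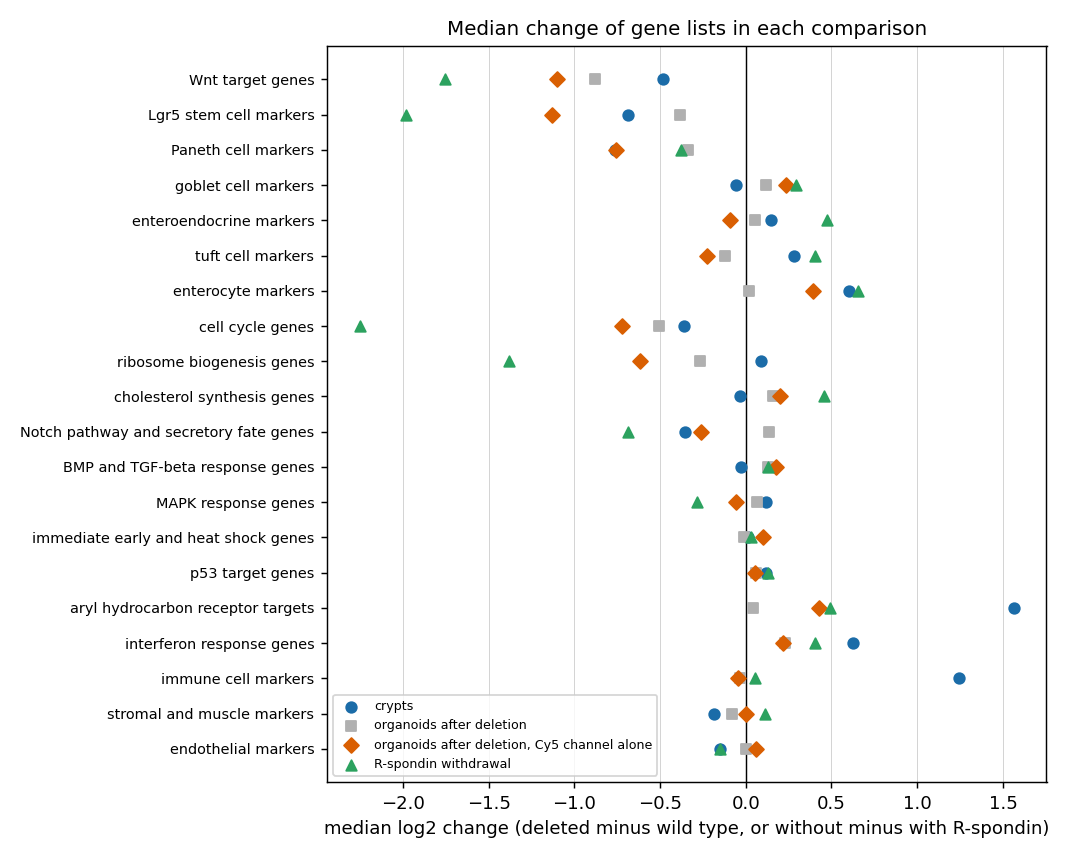
Median log2 change of gene lists in deleted crypts, in deleted organoids by ratio and by Cy5, and after R-spondin withdrawal. Wnt targets lay below 0 in all 4 readings, at -0.48, -0.88, -1.10 and -1.76.

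In the culture kept for 1 day without R-spondin, Wnt targets, stem cell markers and genes of the cell cycle and of ribosome production were lower than in the culture with it, and enterocyte markers were higher. Among genes above background on both arrays the largest falls were Rgcc at -6.34, Pla2g5 at -5.07, Olfm4 at -4.48, the DNA replication genes Uhrf1 at -4.23, Exo1 at -4.00 and Dtl at -3.97, Tgif2 at -4.22, Prelp at -4.10, Cdca7 at -3.92 and Slc12a2 at -3.75. Axin2 was at least 8.62-fold lower. The largest rises were Rgs2 at 3.57, Nup155 at 2.73, Aqp3 at 2.72, Fam3b at 2.65, Enpp3 at 2.44, Sowaha at 2.39, Bcas1 at 2.38, Mgat4c at 2.36, Capn9 at 2.34 and Gk at 2.32. Nup155 depended on its probe, since the other probes gave -1.85 and -1.90.

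With 1 culture per condition there was no test. Of 17157 genes, 1110 were lower and 774 higher by a log2 of 1 or more, and the SD of the differences was 0.656. Over 12874 genes the same count between the 2 wild type organoid cultures was 561 and 505 (SD 0.790), and between the 2 deleted cultures 331 and 278 (SD 0.587). By Cy5 the count was 1192 lower and 954 higher for withdrawal (SD 0.697), 390 and 187 for the wild type pair (SD 0.504) and 235 and 186 for the deleted pair (SD 0.453).

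Wnt targets had a median of -1.76, with 27 of 27 below 0 and 20 at least 2-fold lower, and random lists matched on brightness ranged from -0.19 to 0.24. The medians were -1.98 for stem cell markers (28 of 30 below 0), -2.25 for cell cycle genes (39 of 40, 38 at least 2-fold lower) and -1.38 for ribosome biogenesis genes (27 of 27), all at percentile 0 of the random lists. Cell cycle genes included Mcm3 at -3.37, Mcm2 at -3.32 and Mcm7 at -3.27. Members of the ribosome biogenesis list included Cad at -2.10, Nop56 at -2.09 and Rrs1 at -2.06. Also below the random range were Notch pathway genes at -0.69 (percentile 0.010), Paneth cell markers at -0.38 (0.18) and MAPK genes at -0.28 (2.09). Above it were enterocyte markers at 0.66 (percentile 100), tuft cell markers at 0.41 (99.98), enteroendocrine markers at 0.48 (99.98), cholesterol synthesis genes at 0.45 (99.17), interferon response genes at 0.40 (99.99) and aryl hydrocarbon receptor targets at 0.49 (97.5), at the edge of the range. With genes below background on 1 array at their bounds, the medians were 0.60 for enterocyte markers and 0.39 for tuft cell markers. Inside the range were goblet cell markers at 0.29 (88.1), BMP and TGF-beta genes at 0.13, immediate early genes at 0.03, p53 targets at 0.13, immune cell markers at 0.05, stromal markers at 0.11, endothelial markers at -0.15 and erythroid and mesothelial-fat markers at 0.09.

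By Cy5 some of these lists came out otherwise. Goblet cell markers lay above the random range, at 0.89 (percentile 99.99), and MAPK genes at -0.19 (6.38) and cholesterol synthesis genes at 0.27 (94.0) lay inside it. The medians by Cy5 were -1.88 for Wnt targets, -2.31 for stem cell markers, -2.25 for cell cycle genes, -1.35 for ribosome biogenesis genes, -0.68 for Notch pathway genes and -0.89 for Paneth cell markers. They were 1.41 for enterocyte markers, 0.43 for tuft cell markers, 0.71 for enteroendocrine markers, 0.48 for interferon response genes and 1.001 for aryl hydrocarbon receptor targets, all above the random range. Inside it by both measures were BMP and TGF-beta genes at 0.18, immediate early genes at 0.11, p53 targets at 0.13, immune cell markers at 0.01, stromal markers at 0.16, endothelial markers at -0.17 and erythroid and mesothelial-fat markers at 0.09.

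The random lists hold no variation between cultures, so the lists were also read between the 2 replicate cultures of each deletion group, a comparison added after the results were seen. Of 20 lists, 3 lay outside their random range in the wild type pair and 5 in the deleted pair by ratio, and 8 and 7 by Cy5. The largest size over these 4 readings was 1.66 for Paneth cell markers, 0.62 for goblet cell markers, 0.53 for cholesterol synthesis genes, 0.41 for aryl hydrocarbon receptor targets, 0.35 for Notch pathway genes and 0.27 for MAPK genes. It was 0.31 for Wnt targets, 0.30 for stem cell markers, 0.70 for cell cycle genes, 0.37 for ribosome biogenesis genes, 0.19 for enterocyte markers, 0.24 for enteroendocrine markers, 0.23 for tuft cell markers and 0.16 for interferon response genes. The Paneth cell difference between the cultures with and without R-spondin was thus smaller than that between replicates, and the smaller medians need not come from the withdrawal.

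Many of the top-ranked genes of deleted organoids moved the same way without R-spondin. None of them had passed the test by ratio, and few by Cy5. The 100 genes most clearly lower in deleted organoids had a median of -1.49 without R-spondin, with 81 of 100 below 0, and the genes most clearly higher had 0.56, with 75 of 87 measured above 0. With the lists chosen by Cy5 the medians were -1.97 (91 of 96) and 0.50 (69 of 88). All 4 medians lay outside the matched random lists, at percentiles 0 and 100. Those lists hold no variation between cultures, and the sets were not read between replicate cultures. The lower median rested on both wild type cultures and was 0.03 without replicate 1 and 0.14 without replicate 2, and it was -0.38 with the first version of the processing. The higher median was 0.26 to 0.41 without a replicate and 0.14 with the series matrix, inside the random range. Across 12193 genes the changes had a Spearman correlation of 0.370 by ratio and 0.6251 by Cy5 against the withdrawal ratio, and 0.641 with both by Cy5, where genes are not independent replicates.

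**Figure D3:**
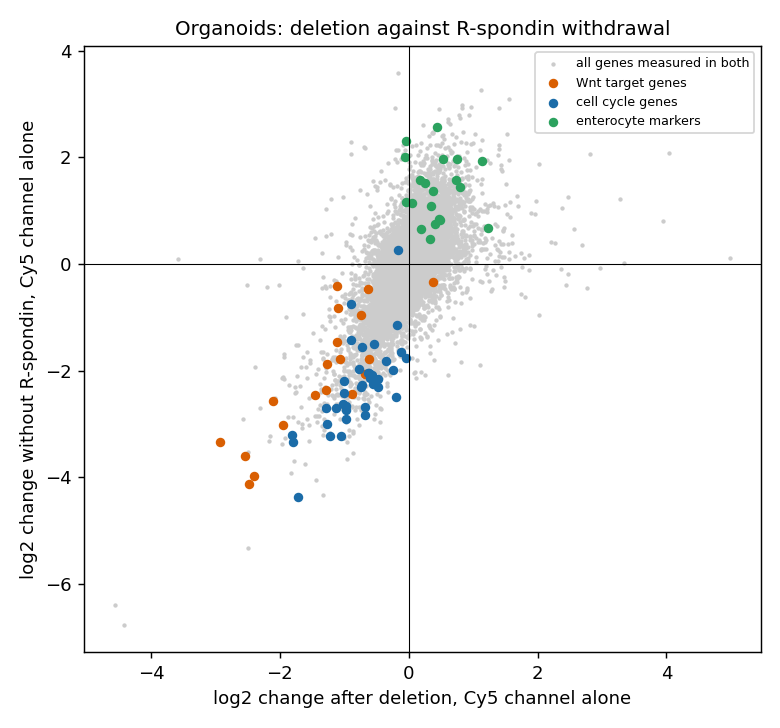
Log2 change in deleted organoids against log2 change without R-spondin, both by Cy5 alone, with all genes measured in both in grey, Wnt targets in orange, cell cycle genes in blue and enterocyte markers in green. The Spearman correlation across genes was 0.641.

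The 100 top-ranked genes per direction in crypts, most of which did not pass the test, moved the same way on the median without R-spondin, by an amount that depended on the processing. Their medians in deleted organoids were smaller, a difference that was not tested. The 100 genes lower in crypts had a median of -0.83 without R-spondin (68 of 90 below 0, percentile 0), and the 100 higher had 0.69 (66 of 77 above 0, percentile 100). The higher median lay inside the random range with processed signals, at 0.33, and with the series matrix, at 0.28. Without crypt replicate 1 the lower median was -0.27 and the higher 0.27, and without replicate 2 they were -0.60 and 0.85. In deleted organoids the lower set had a median of -0.10 by ratio (52 of 84 below 0, camera adjusted p 1.79e-05, estimated 0.210) and the higher set 0.08 (48 of 73 above 0, adjusted p 0.130). By Cy5 the medians were -0.42 (60 of 84, camera adjusted p 2.05e-09) and 0.27 (53 of 73, 4.27e-06), and both calls held with an estimated correlation at 0.0375. The lower median by ratio was 0.02 without crypt replicate 1. Spearman correlations across genes were 0.137 between crypts and organoids by ratio, 0.297 by Cy5, and 0.332 between crypts and withdrawal.

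The deletion effect differed between crypts and organoids for 3 genes of enzymes that metabolise foreign compounds, a count that rested on the processing. In the joint limma fit of 11009 genes, Akr1b8, Gsta3 and Cbr3 rose more in crypts, with 3 genes higher and 0 lower at an adjusted p of 0.0407, and 377 lower and 294 higher at an unadjusted p under 0.05. With organoids by Cy5, 6 genes were higher and 5 lower in crypts, and 3 genes were shared by both fits. Limma called 0 with no dim probe filter (1518 at an unadjusted p under 0.05) and 0 with the first version (276 unadjusted), and the count by ratio ranged from 0 to 102 without a replicate. As a list, the aryl hydrocarbon receptor targets differed in camera by 1.21 by ratio (adjusted p 0.000547) but not with an estimated correlation (0.460 by ratio, 0.353 by Cy5). Changes of 2 placed in the raw signals came back as 1.90 in crypts and 1.20 in organoids by ratio. Part of a difference by ratio can thus come from the measure.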

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

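In this part the tests of list differences between crypts and organoids, the measures by Cy5 alone and the dye test on the xenobiotic-response genes were chosen only after the results were seen, and the other tests were chosen before.

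The Lgr5 ratio on 1 crypt array lay far from the other 3. On the array of replicate 1 with deleted RNA in Cy5 it was -2.27, and the others ranged from -1.54 to -1.42, a gap of 0.853 of the whole range. For independent values chance marks about 1 in 20 groups this way, which would be 2.15 of the 43 values examined, and 1 stood out. The crypt arrays are dye-swapped pairs of the same RNA, so that rate need not hold here. No explanation was tested for it.

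The effect of deletion differed between crypts and organoids for 3 genes by ratio, tested in the joint limma fit. The crypt minus organoid difference was 3.94 for Akr1b8 (SE 0.28), 4.03 for Gsta3 (SE 0.31) and 4.97 for Cbr3 (SE 0.38), each at an adjusted p of 0.0407. All 3 were higher in 2 of 2 crypt replicates, while their organoid changes were 0.51, -0.34 and -0.004.

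With organoids read by Cy5 alone, limma found the difference for 11 genes. Positive differences were Cbr3 at 4.48, Gsta3 at 4.15 and Akr1b8 at 3.87 (adjusted p 0.00429 each), Rgcc at 4.12 (0.0146), Ces1g at 3.98 (0.00762) and Aldh4a1 at 2.68 (0.0408). Negative differences were Nrn1 at -5.57 (0.00403), H2-Bl at -3.75 (0.00563), Npl at -3.70 (0.0377), Zfp503 at -3.48 and Gas6 at -3.08 (0.0412 each). Zfp503 lies outside the naming rule and was chosen after its values were seen. Nrn1 changed by -0.58 in crypts and 4.98 in organoids, H2-Bl by 0.28 and 4.04, Npl by -0.94 and 2.76, Zfp503 by -0.60 and 2.88, Gas6 by 0.27 and 3.35, and Rgcc by -0.44 and -4.56.

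As lists, 7 differed between the systems by ratio, tested with camera on the crypt minus organoid effect. The median difference was 0.60 for enterocyte markers (adjusted p 3.43e-07), 0.79 for immune cell markers (1.09e-05), 0.38 for ribosome biogenesis genes (0.000177), 0.79 for tuft cell markers (0.000476), 1.21 for aryl hydrocarbon receptor targets (0.000547), -0.69 for Notch pathway genes (0.0110) and 0.29 for interferon response genes (0.0132). With an estimated correlation between genes none of the 7 passed, at camera adjusted p-values of 0.496 for the Notch list and 0.460 for the other 6. By ratio the systems are not on one scale, since a placed change of -2 came back as -1.82 in crypts and -1.04 in organoids. An equal effect could thus differ by ratio, and by Cy5 the organoid value was -1.75. The joint fit measured 5 aryl hydrocarbon receptor targets and 13 immune cell markers, fewer than the crypts alone. Organoids were grown from crypt cells as epithelia, so their immune cell markers could not show a change in immune cells. The immune cell difference therefore does not compare an effect of deletion between the systems. By Cy5 the Notch difference was -0.06 (camera adjusted p 0.491). The other 6 passed by Cy5, with smaller differences of 0.20 for enterocyte markers (0.00507), 0.35 for tuft cell markers (0.000328) and 0.76 for aryl hydrocarbon receptor targets (0.00868), and larger ones of 0.71 for ribosome biogenesis genes (3.76e-12), 0.89 for immune cell markers (4.46e-08) and 0.47 for interferon response genes (0.0400). By Cy5 alone camera also called stem cell markers at 0.40 (0.000602), cell cycle genes at 0.37 (1.71e-05), cholesterol synthesis genes at -0.29 (0.0259) and BMP and TGF-beta genes at -0.17 (0.0400). None of the calls by Cy5 passed with an estimated correlation, at 0.353 to 0.531. Wnt targets did not differ by ratio, at 0.25 (camera adjusted p 0.0729), and were less reduced in crypts by Cy5, at 0.68 (2.48e-08, estimated 0.353). Lgr4 itself fell less in crypts than in organoids by Cy5, but more than in organoids by ratio. The extent of deletion was not compared between the systems, and the list differences cannot be separated from it.

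The first pattern weighed is the rise of xenobiotic-response genes in deleted crypts. For the aryl hydrocarbon receptor targets, a list fixed before the data were examined, dye bias is argued against. Their median on the 4 arrays turned to deleted over wild type ranged from 1.20 to 2.38, above 0 in both dye orientations. A general effect of losing Lgr4 and Lgr5 would raise the targets in deleted organoids too. Their median there was 0.43 by Cy5, over 5 targets, with random lists reaching 0.37, which lies between the bounds set in advance of 0.29 and 0.58 and decides nothing. Those bounds were set for Cy5, and by ratio, the planned measure, the median of 5 targets was 0.04. Without R-spondin, where the labels name no Cre, the targets were higher by 0.49 by ratio and 1.001 by Cy5 in 1 culture, where replicate cultures differed by up to 0.41. The agent that switches on Cre in the deleted mice is a candidate explanation, since that promoter responds to xenobiotics and the organoids used another Cre. The crypt minus organoid median was 0.76 by Cy5 (camera adjusted p 0.00868, estimated 0.353), as this explanation needs. It cannot be told apart from an effect of deletion that occurs in the animal alone, because the tissue and the way of inducing Cre changed together, and the labels do not say whether wild type mice received the agent.

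The second pattern weighed is the rise of immune cell markers in deleted crypts, with a median of 1.24 that included Ccl5 at 2.46 and Cd7 at 2.11. Dye bias is argued against, since the median on the 4 turned arrays ranged from 0.83 to 1.47. A larger share of all non-epithelial cells is argued against as well, because 10 stromal and muscle markers had a median of -0.18 and 5 endothelial markers -0.15. The 2 measured erythroid and mesothelial-fat markers, too few to test, went the other way at 0.80, but were at -0.08 and 0.10 on the arrays of replicate 2. A larger share of immune cells alone, for example of T cells lying within the epithelium, may have remained with the crypts and stays open as a hypothesis, as does a higher expression in the cells already there. The labels name no sort that would remove such cells, and neither possibility was tested. The agent given to the mice stays open here too, for the reason given above.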

How the results depend on the processing

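The alternatives by Cy5 alone and with the first version of the processing, and leaving out replicates for the difference between systems and for the signatures without R-spondin, were tests chosen only after seeing the data. Below, the crypt-lower, crypt-higher, organoid-lower and organoid-higher sets are the 100 top-ranked genes per direction after deletion, most or all of which did not pass the test. Where a value moved, the cause was not tested unless a reason is given.

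The direction of the Wnt target median held under every alternative run. It ranged from -0.64 to -0.30 in crypts, from -1.10 to -0.23 in organoids and from -1.93 to -1.56 without R-spondin. Without a replicate it ranged from -0.47 to -0.42 in crypts and from -0.80 to -0.52 in organoids. At -0.48 and -0.88, the crypt and organoid medians missed the threshold with an estimated correlation (camera adjusted p 0.622 and 0.524) and with fry (0.218 and 0.194), which test the same values in another way. Over all alternatives the adjusted p ranged from 9.05e-07 to 0.622 in crypts and from 1.40e-18 to 0.524 in organoids.

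The number of genes called in crypts, 0 lower and 6 higher, depended strongly on the processing. It was 245 and 334 with 4 arrays and the replicate as a random block, 281 and 340 with a dye term added, 28 and 72 with deleted RNA in Cy5 alone, 198 and 232 with deleted RNA in Cy3 alone, and 7 and 35 with a joint fit sharing the spread. Changes to the signals gave 10 and 39 with no background subtraction, 338 and 448 with processed signals, 55 and 278 with median centring, 20 and 74 with the mean of all probes, 159 and 294 with the series matrix, and 4 and 18 with the first version. With no filter on dim probes limma called 0 lower and 0 higher (1342 and 1400 at an unadjusted p under 0.05), and 27799 genes were tested. Without crypt replicate 1 it called 0 and 0 (1654 and 986 unadjusted), and without replicate 2 it called 0 and 0 (529 and 529 unadjusted), a range of 0 to 0 with the lone replicate assumed to vary like the organoid groups. Cbr3, Akr1b8, Gsta3 and Ces1g missed the threshold without either replicate, with limma adjusted p-values from 0.0566 to 0.207, and over all alternatives Cbr3 ranged from 9.45e-47 to 0.437. Lgr4 and Lgr5 passed with processed signals, median centring and the series matrix.

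In organoids, limma called 0 lower and 0 higher, but 1 and 4 by Cy5 and 2 and 11 with the series matrix. Without a replicate the counts ranged from 0 to 122 lower and from 0 to 9 higher, at 122 and 9 without wild type replicate 1, 65 and 3 without wild type replicate 2 and 0 lower and 0 higher without deleted replicate 1 (102 and 267 unadjusted) or 2 (211 and 279). The lone culture is assumed to vary like the other groups. With the slide as a block limma called 0 and 0 (334 and 492 unadjusted), and each slide alone gave values but no test. Genes whose effect differed between the systems, 3 in all, were 12 with processed signals, 43 with the series matrix, 11 by Cy5, and in limma 0 with no dim probe filter (1518 unadjusted) and 0 with the first version (276 unadjusted). Without a replicate their number ranged from 0 to 102, at 102 and 69 without wild type replicates 1 and 2 and in limma 0 without any of the other 4 (466 to 1678 unadjusted).

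Without R-spondin, 1110 genes were lower and 774 higher at a size of 1, and 2234 and 2160 at 0.58, where a smaller size admits more genes. The higher count was 1465 with processed signals and 1265 with the series matrix. Processed signals placed the median of all genes at 0.12 in organoids and 0.18 without R-spondin, the series matrix at 0.16 and 0.12, and median centring at 0.15 in crypts and 0.10 without R-spondin.

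The crypt-lower set in organoids, at -0.10, turned to 0.011 with the series matrix, where camera still read it as lower (adjusted p 3.25e-05), and ranged from -0.20 to 0.021 without a replicate, at 0.021 without crypt replicate 1 (camera adjusted p 0.940). Over all alternatives its camera adjusted p ranged from 2.05e-09 to 0.940. The crypt-higher set in organoids, at 0.08, passed camera at 0.14 with 200 genes, 0.27 by Cy5, 0.24 with median centring, 0.11 with no background subtraction, 0.13 with no dim probe filter, 0.23 with the first version and 0.19 with processed signals. Without a replicate it ranged from 0.031 to 0.14, and it passed at 0.12 and 0.13 without crypt replicates 1 and 2. With called genes alone it was -0.004, without a call.

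Without R-spondin the crypt-lower set, at -0.83, gave -0.98 with 50 genes, -0.70 with 200, -0.49 with the mean of all probes, -0.41 with median centring, -0.36 with processed signals, -0.54 with the series matrix and -0.60 to -0.27 without a replicate. The crypt-higher set, at 0.69, gave 0.55 with 50 genes, 0.49 with called genes alone, 0.92 by Cy5, 0.48 with median centring, 0.81 with no dim probe filter, 0.27 to 0.85 without a replicate, and 0.33 with processed signals and 0.28 with the series matrix, both inside the random range. The organoid-lower set, at -1.49, gave -0.74 with 50 genes, -2.18 by Cy5, -1.27 with the mean of all probes, -1.73 with median centring, -1.26 with no background subtraction, -1.09 with no dim probe filter, -0.38 with the first version, -1.88 with processed signals and -2.04 with the series matrix. Without a replicate it ranged from -1.79 to 0.14, turning to 0.03 and 0.14 without wild type replicates 1 and 2. The organoid-higher set, at 0.56, gave 0.41 with 200 genes, 0.45 with the mean of all probes, 0.42 with no dim probe filter, 0.36 with the first version, 0.33 with processed signals, 0.26 to 0.41 without a replicate, and 0.14 with the series matrix, inside the random range.

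Other values, called or of a size of 1 or more under 1 of the 2 settings, turned sign. Notch pathway genes in organoids were at -0.26 by Cy5, tuft cell markers in organoids at 0.033 with processed signals and 0.039 with the series matrix, and enteroendocrine markers in crypts at -0.073 without crypt replicate 2. Without R-spondin Nup155 was at -0.34 with the mean of all probes, which averages the probes that disagree. Mptx1 was at 0.58 with processed signals and 0.52 with the series matrix, against -1.24, and Reg3g at -0.90 and -0.96, against 1.20. Over lists and alternatives, 708 list medians held their side of the threshold or had none, 60 of them with a change of sign and no call under either setting, while 43 lost and 20 gained a call, 14 untested ones moved and 4 called ones turned. Of the named gene values 7092 held in this sense, 505 of them with a change of sign, 13 lost and 260 gained a call, 68 moved, 3 of them with a change of sign, and 5 turned.

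Without crypt replicate 1 the crypt calls of Paneth cell markers (-0.12), tuft cell markers (0.16) and cell cycle genes (-0.18) were lost in camera and stromal markers passed (-0.66). Without crypt replicate 2 Notch pathway genes (-0.29) and immediate early genes (0.22) passed. In organoids the tuft cell call was lost without wild type replicate 1 (-0.22), wild type replicate 2 (-0.01) or deleted replicate 2 (-0.18), and the Paneth cell call without wild type replicate 2 (-0.07). Cholesterol genes passed without wild type replicate 1 (0.38) or deleted replicate 2 (0.38), and Notch pathway genes without deleted replicate 1 (0.24). On the organoid deletion arrays 3.66% to 4.26% of spots were above background in Cy3, and a placed change of -2 came back as -1.04 by ratio. The placed change left the Cy3 signals as they were, so it does not show that they caused the loss.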

Other observations

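In this part the comparison with the Cy5 channel was chosen only after the state of the Cy3 reference channel had been seen, but both tests below were written before their results.

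No gene passed the limma test by ratio in deleted organoids, with 497 genes at an unadjusted p under 0.05, although the Wnt target median was -0.88, a list call that was lost with an estimated correlation (camera adjusted p 0.524). Of the technical explanations, the Cy3 reference channel, bright but with few spots above background, is a candidate. When a change of -2 was placed in the deleted Cy5 signals of 200 genes, the SD over genes of the recovered change was 1.76 times larger by ratio than by Cy5. The median size recovered was 0.71 smaller, at -1.04 by ratio and -1.75 by Cy5. Both values passed the bounds set for this explanation, which may account for part of the missing calls. The placed change left the Cy3 signals as they were. The test thus compared the 2 measures, normalisation included, and did not isolate the channel. The same arrays gave 5 calls by Cy5, and with the ratios of the series matrix limma called 2 genes lower and 11 higher. The number of arrays alone thus did not prevent every call. As a limit on calls by the planned ratio, the number of arrays stays open beside the channel. In simulated organoid data with 200 genes changed by 2, limma called 0 when spread was drawn from the fitted prior and 179 when each gene had its shrunken spread, so that the result depended on the assumed spread. No biological explanation was tested for this pattern.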
